A study of Mus musculus with 13 samples.

How the data were processed

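Gene expression was measured on 13 Illumina mouse BeadChip arrays of sorted cochlear cells from 3-day-old Math1-nGFP mice: HC (4 arrays), GER (3), DC (2), CD271high (3) and BM (1). Per the labels, RNA was extracted with a Macherey-Nagel XS kit, checked on a Bioanalyser, amplified and biotin-labelled with an Ambion MessageAmp kit, and hybridised. The arrays lay on 2 beadchips: HC A, GER A and B, DC A and B, CD271high B and C and BM on beadchip 1, and HC B, C and D, GER C and CD271high A on beadchip 2. Populations were taken from the sample titles. The description of GER C gives the replicate letter A, and the title was followed. The labels do not say whether the replicates are separate animals.

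The deposited scanner table held, per the file headers, the mean bead intensity of 25697 probes per array, not normalized between arrays and not background-subtracted, with a lowest raw signal of 117. Beside each signal it held a detection p-value, per the file headers, and 2 further columns per array, the bead standard error and bead count, that are not used here. A second deposited table held log2 values that the authors had quantile normalized, with a median of 8.143 on every array and the ranks of the scanner signal (Spearman's rho 1). The scanner software and its settings are not given in the sources used here. Probes were joined to the gene symbols of the GRCm38.p6 gene table by RefSeq accession or, failing that, by Entrez ID. That matched 24358 probes, and 1339 kept the symbol of the file. The array covered 18038 genes, 4910 of them with more than 1 probe.

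The main values were computed from the scanner table. In R 4.3.3 with limma 3.58.1, neqc corrected the background from the detection p-values (normexp, offset 16), quantile normalized the arrays and took log2. Probes with a detection p under 0.01 on at least 2 arrays were kept (13192), and each gene was represented by its probe with the highest mean, which left 10088 genes and removed 7950. Between 40.2% and 45.2% of probes were detected per array, and the median SE of a difference was 0.176 for HC, 0.237 for GER against DC and 0.175 for CD271high, which with the number of arrays sets the precision.

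For each gene limma's lmFit fitted 1 mean per population over the 13 arrays (8 residual degrees of freedom), and eBayes moderated the variances (3.7 prior degrees of freedom). There were 3 tested comparisons: HC against the mean of the GER and DC means, GER against DC, and CD271high against the mean of the HC, GER and DC means. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05 on the adjusted p. BM, with 1 array, was compared with GER and DC without a test: its value was set against the range of the 5 arrays, and the median of each list against 10000 random lists matched on level, given as a percentile. The fit was checked on simulated data in which, for each comparison, 100 genes were shifted by 1 and another 100 by 2 on the log2 scale. Of these, 77% and 99% were recovered for HC, 49% and 89% for GER against DC, and 77% and 98% for CD271high. There were 10, 7 and 5 false calls among unchanged genes. The simulated genes varied independently and few of them were shifted, unlike the measured ones, so these figures need not hold for the real comparisons.

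Gene lists were fixed before the data were examined, as were the groups, tests, thresholds and most alternatives. The 27 lists covered hair cells, ribbon synapses and vesicle release, supporting cells, Deiters cells, pillar cells, the greater epithelial ridge, the lesser epithelial ridge with Claudius cells and outer sulcus, tectorial membrane and cochlear matrix, gap junctions, the Notch, Wnt and Fgf pathways, the cell cycle, Cdk inhibitors, stem cell-associated genes, epithelium, macrophages, Schwann and satellite glia, neurons, mesenchyme, bone and cartilage, endothelium, pericytes and smooth muscle, erythroid cells, melanocytes and stria vascularis, the dissociation response and the sort markers. They were written from general knowledge, held 518 entries, of which 490 matched the array and 392 passed the filter, and overlap: of 340 genes tested, 38 stand in more than 1 list. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 81 tests of 27 lists in 3 comparisons, beside camera with an estimated correlation and fry. A list score is the mean over its genes of the log2 level minus the mean of that gene over the 13 arrays.

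The genes named were chosen by a rule fixed before the data were examined: per comparison the 10 highest and 10 lowest by log2 difference among those that passed and whose sides did not overlap on any array, leaving out clone, locus and predicted names; in each list up to 6 members with the largest difference; and the sort markers. For BM the 10 highest and lowest outside the range of the 5 arrays were taken. The examples given are drawn from these. Genes undetected on every array of 1 side are given as lower bounds, with that side set to the lowest level detected on each array, or without a fold where no bound results. Where a side was detected on only some of its arrays, the fold rests partly on values near background and is uncertain.

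Alternatives covered the normalization (quantile without background correction, median scaling, the deposited log2 values), the filter on dim probes (none, a detection p under 0.05, at least 4 arrays), the mean of all probes of a gene, a 2-fold minimum, fits of the compared groups alone, array weights, an intensity trend with robust variances, the beadchip as a block, as a random effect and within each beadchip, the replicate letters as a block, single reference populations, and each array left out in turn. The deposited log2 values gave the same counts as quantile normalization without background correction. Tallies over alternatives count the 2 separately, though they are in effect 1 analysis. For CD271high the fit of the compared groups alone gave the main counts again. Leaving out each array was planned, HC replicate D was singled out among them after seeing the data, and the HC count without the genes of other cell types was added then. Left out were the bead-level columns, since the tests use the spread between arrays, and Epcam, which is not analysed here. Results for 2 single genes are not reported here, and these genes were left out of the check for 1 array far from the others after its result was seen; they stay in the lists and counts.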

Results

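Cochleae of 3-day-old mice carrying the Math1-nGFP reporter, which marks hair cells with nuclear GFP, were dissociated and sorted into 5 populations by GFP and the surface proteins CD271, CD146 and CD326. RNA of each sort was hybridised to an Illumina BeadChip array, 13 arrays in all. HC, the GFP-positive hair cells, had 4 arrays. GER, the cells of the greater epithelial ridge medial to the organ of Corti (low CD271, high CD146, CD326-positive), had 3. DC, a gate for Deiters' and Claudius cells (low CD271, low CD146, CD326-positive), had 2. CD271high, the GFP-negative cells with the most CD271, which the labels call suspected macrophages, had 3. BM, the cells from below the basilar membrane (low CD271, CD326-negative), had 1. Between 10343 and 11618 of the 25697 probes were detected per array, 40.2% to 45.2%. The median raw signal per array lay between 252.5 and 323.9. Values are log2 levels after normalization, each ± is a standard error (SE) of the fitted difference unless named otherwise, and the small number of arrays limits their precision. Whether the replicates came from separate animals is not stated, so each p-value measures the spread between these samples, which may be technical.

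Arrays of 1 population resembled each other more than arrays of another population. Pearson's r across genes, which are not independent replicates, was 0.959 to 0.983 among the HC arrays, 0.978 to 0.982 among GER, 0.987 between the DC arrays and 0.979 to 0.983 among CD271high. GER and DC were the closest pair of populations, with a mean r of 0.965, and HC and BM the farthest, with 0.761.

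The transcripts of the proteins used for sorting were read first. Atoh1, the Math1 gene whose enhancer drives the reporter, was detected on 2 of 4 HC arrays and on no other array. It was near background on every array, so no difference is given; it passed as higher in HC than in GER and DC (adjusted p = 0.00052, 4 HC arrays against 3 GER and 2 DC arrays), but not within beadchip 2 (adjusted p = 0.13). Ngfr, which encodes CD271, was 6.37-fold higher in DC than in GER (GER minus DC -2.67 ± 0.35, adjusted p = 0.00096). In CD271high, Ngfr was 3.92-fold lower than in HC, GER and DC (-1.97 ± 0.26, adjusted p = 6.6e-05). Its mean log2 level was 9.01 against 12.49 in DC, 10.61 in HC and 9.82 in GER. Within beadchip 2, which holds 1 CD271high array and no DC array, its difference from HC and GER was -1.13. Against GER alone Ngfr differed by -0.82 (adjusted p = 0.07), which did not pass. Mcam, which encodes CD146, was 3.02-fold higher in GER than in DC (1.59 ± 0.26, adjusted p = 0.0036), the direction of the sort. Epcam, which encodes CD326, is not analysed here.

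**Figure D1:**
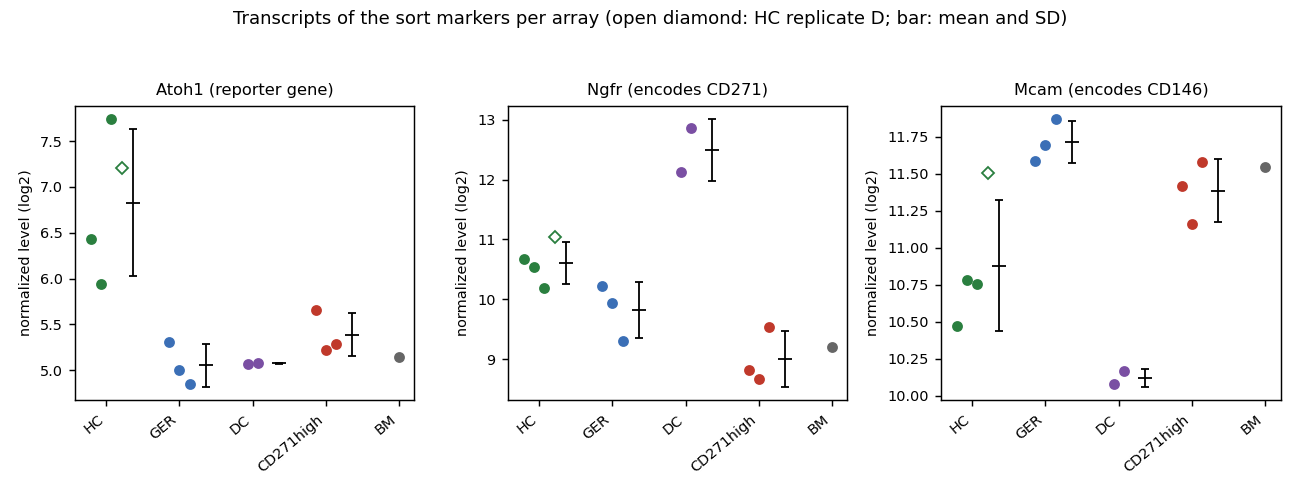
Normalized log2 level of Atoh1, Ngfr and Mcam on each of the 13 arrays by population; bars give the mean and SD, and HC replicate D is an open diamond. Ngfr was highest on the 2 DC arrays (mean 12.49) and lay at a mean of 9.01 in CD271high.

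HC were compared with GER and DC to ask which transcripts set the hair cells apart from the GFP-negative epithelial cells beside them. Genes of hair cell function were far higher in HC. Otof, which encodes otoferlin, the calcium sensor of hair cell exocytosis, was 151-fold higher (7.24 ± 0.22, adjusted p = 1.7e-10) and was detected on 3 of the 5 GER and DC arrays. Pvalb, which encodes the calcium buffer parvalbumin, was 92.6-fold higher (6.53 ± 0.26, adjusted p = 1.6e-09). Among single genes, Bmp4, which encodes a secreted morphogen, was 14.3-fold lower (-3.84 ± 0.33, adjusted p = 1.7e-06), and P4ha2, which encodes a subunit of collagen prolyl hydroxylase, 8.54-fold lower (-3.09 ± 0.20, adjusted p = 1.5e-07).

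Hair cell genes were the clearest group. Of 34 measured members of the hair cell list, 31 were higher, 0 lower and 3 did not pass (31 higher and 0 lower adjusted over the list alone), with a mean log2 difference of 4.12 (adjusted p = 1.8e-25, and adjusted p = 0.0023 with an estimated correlation). Where a gene was not well above background on any array of 1 side, its fold is a lower bound, with that side set to the lowest level that counted as detected on each array. By this bound Gfi1, a transcription factor of hair cell maturation, was at least 61.4-fold higher in HC (adjusted p = 9.2e-11), and Myo7a, the stereocilia myosin, at least 55.4-fold (adjusted p = 1.8e-10). With such genes at their bounds the median of the list was 3.65. Chrna10, a subunit of the receptor for efferent acetylcholine, was 114-fold higher (6.83 ± 0.21, adjusted p = 2.1e-10). Of the 18 genes for ribbon synapses and vesicle release, 13 were higher, 1 lower and 4 did not pass (13 and 1 adjusted over the list alone; mean 2.15, median 1.65 or 1.23 with undetected sides at their bounds, adjusted p = 9.4e-07, and adjusted p = 0.0081 with an estimated correlation). Cplx1, a complexin that clamps vesicle fusion, was at least 49.4-fold higher (adjusted p = 2.2e-10), and Slc17a8, the vesicular glutamate transporter of inner hair cells, 18.7-fold (4.22 ± 0.17, adjusted p = 2.2e-09). Among the genes with the largest differences of all were Cpne9, which encodes a copine, a calcium-dependent membrane-binding protein, at least 76.4-fold higher (adjusted p = 1.8e-11), and Atp2a3, a calcium pump of the endoplasmic reticulum, 139-fold (7.12 ± 0.30, adjusted p = 2.2e-09; detected on 2 of 5 GER and DC arrays). The probe of Ccl21a, at least 71.2-fold higher, cannot be separated with certainty from its near-identical paralogs.

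Signalling genes moved in both directions. In the Notch list of 22 genes, 6 were higher, 10 lower and 6 did not pass (7 and 10 adjusted over the list alone), and the list did not pass as a whole (mean 0.37, median -0.13, adjusted p = 0.92). The ligand gene Jag2 (12-fold higher, 3.59 ± 0.22, adjusted p = 8.2e-08) and Mfng, a modifier of Notch receptors (44-fold higher, 5.46 ± 0.36, adjusted p = 1.4e-07), rose, while the Notch targets Hes1 (-1.20 ± 0.17, adjusted p = 0.00013) and Hey1 (-0.57 ± 0.14, adjusted p = 0.0068) were lower. Of 11 genes of the Fgf list, 2 were higher, 2 lower and 7 did not pass (2 and 2 adjusted over the list alone; mean 0.53, median -0.13, adjusted p = 0.88). Fgf8, the inner hair cell signal to pillar cells, was 91.3-fold higher (6.51 ± 0.19, adjusted p = 1.7e-10; detected on 1 of 5 GER and DC arrays). Of 8 Cdk inhibitor genes, 3 were higher, 2 lower and 3 did not pass (3 and 2 adjusted over the list alone; mean 0.33, adjusted p = 0.51). Cdkn2d, which keeps hair cells out of the cell cycle, was 6.04-fold higher (2.59 ± 0.18, adjusted p = 3.2e-07), and Cdkn1b, the inhibitor of supporting cell division, was not well above background on any HC array and at least 1.52-fold lower (adjusted p = 0.0043). Within beadchip 2, with 1 reference array, Hes1, Cdkn1b and Hey1 did not pass (adjusted p = 0.23, 0.74 and 1), and the difference of Hey1 was 0.003. Against GER alone Hey1 (-0.34, adjusted p = 0.12) and Cdkn1b (-0.74, adjusted p = 0.11) did not pass either. In the neuron list of 16 genes, 8 were higher, 5 lower and 3 did not pass (8 and 5 adjusted over the list alone; mean 1.28, median 0.71 or 0.21 at the bounds, adjusted p = 0.059). That p was under 0.05 in 4 of 32 alternatives: against DC alone (mean 1.44, 0.011), without HC A (0.043), without DC A (0.046) and by fry (4.6e-08). Rbfox3 and Nefm, markers of nerve cells, were at least 31.3-fold and at least 28.7-fold higher in HC.

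Epithelial, Wnt, GER and stem cell-associated genes were lower in HC. Of 17 epithelium genes, 1 was higher, 10 lower and 6 did not pass (1 and 11 adjusted over the list alone; mean -0.82, adjusted p = 0.0027, but adjusted p = 0.06 with an estimated correlation). Lower ones included Krt19, a keratin (-2.50 ± 0.15, adjusted p = 8.4e-08), and Cldn4, a tight junction claudin (-1.88 ± 0.16, adjusted p = 1.4e-06). The Wnt list of 29 had 2 higher, 14 lower and 13 that did not pass (2 and 14 adjusted over the list alone; mean -0.68, adjusted p = 0.0079, but adjusted p = 0.18 with an estimated correlation). Rspo3, a secreted enhancer of Wnt signalling, was at least 2.96-fold lower (adjusted p = 1.8e-05), and the ligand gene Wnt5a fell by 1.82 (SE 0.21, adjusted p = 2.1e-05). Of 12 genes of the GER list, 0 were higher, 9 lower and 3 did not pass (0 and 9 adjusted over the list alone; mean -1.22, adjusted p = 0.0087, but adjusted p = 0.18 with an estimated correlation). Fst, which encodes the activin antagonist follistatin, was not well above background on any HC array and at least 8.01-fold lower (adjusted p = 1e-07), and Epyc, a matrix proteoglycan, was lower by the fitted difference of -1.86 ± 0.33 (adjusted p = 0.00057). Of 13 stem cell-associated genes, 0 were higher, 8 lower and 5 did not pass (0 and 8 adjusted over the list alone; mean -0.70, adjusted p = 0.029, but adjusted p = 0.25 with an estimated correlation). Axin2, a Wnt target, differed by -1.39 ± 0.20 (adjusted p = 0.00011) and Sox9, a progenitor transcription factor, by -0.84 ± 0.15 (adjusted p = 0.00075). Within beadchip 2 the difference of Axin2 was -1.12 (adjusted p = 0.16). Without HC replicate A the stem cell-associated list no longer passed (mean -0.62, adjusted p = 0.053), nor against GER alone (mean -0.60, adjusted p = 0.094).

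Genes of other cell types were read beside these groups. Of 14 endothelium genes, 9 were higher in HC, 0 lower and 5 did not pass (12 and 0 adjusted over the list alone; mean 1.49, adjusted p = 0.0027, but adjusted p = 0.63 with an estimated correlation). Esam, an endothelial adhesion molecule, differed by 3.09 ± 0.62 (adjusted p = 0.0015; detected on 2 of 5 GER and DC arrays). The endothelium list scores of the HC arrays ranged from -0.55 (C) to 1.48 (D), that of GER C was 0.65, and within beadchip 2, where GER C is the only reference array, the mean difference was 0.04 (adjusted p = 0.79) and that of Esam 0.27 (adjusted p = 0.91). Against GER alone Esam differed by 1.77 (adjusted p = 0.061). Of 23 macrophage genes, 5 were higher, 1 lower and 17 did not pass (4 and 1 adjusted over the list alone; mean 0.63, adjusted p = 0.055), and the list passed in 8 of 32 alternatives, among them against GER alone (mean 0.95, adjusted p = 0.0086) but not against DC alone (mean 0.31, adjusted p = 0.32). Laptm5, a lysosomal membrane protein of blood cells (23.3-fold, 4.54 ± 0.29, adjusted p = 1.1e-07), and C1qb, a chain of complement C1q (19.1-fold, 4.26 ± 0.32, adjusted p = 4.7e-07; detected on 1 of 5 GER and DC arrays, so the fold is uncertain), were the 2 members with large differences. HC replicate D stood apart from replicates A, B and C in several of these lists. Its score was 0.50 for Schwann and satellite glia against -1.29, -1.01 and -1.60, 1.26 for pericytes against -0.62, -0.77 and -0.80, 0.02 for mesenchyme against -0.71, -0.70 and -0.81, and 0.38 for the cell cycle against -0.59, -0.60 and -0.81. The glia list had 1 higher, 2 lower and 12 that did not pass in HC (1 and 2 adjusted over the list alone; mean 0.00, median -0.08, adjusted p = 0.92). The cell cycle list of 24 had 4 higher, 3 lower and 17 that did not pass (4 and 3 adjusted over the list alone; mean 0.38, adjusted p = 0.34).

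Some lists did not pass in HC though many members did. The dissociation response, the immediate-early genes that cell isolation induces, had 2 of 19 higher, 11 lower and 6 that did not pass (2 and 13 adjusted over the list alone; mean -0.70, adjusted p = 0.098). It passed in 3 of 32 alternatives (range 0.017 to 0.9). The lesser ridge, Claudius and outer sulcus list had 1 of 12 higher and 6 lower (mean -0.96, adjusted p = 0.19). The tectorial membrane and matrix list had 0 of 11 higher and 6 lower (mean -0.60, adjusted p = 0.11). It passed in 3 of 32 alternatives: with median scaling (adjusted p = 0.044), with no filter on dim probes (adjusted p = 0.044) and by fry (adjusted p = 4e-06). The bone and cartilage list had 0 of 9 higher and 4 lower (mean -0.76, adjusted p = 0.099) and the melanocyte and stria list 1 of 8 higher and 5 lower (mean -0.58, adjusted p = 0.45). Bone and cartilage passed in 2 of 32 alternatives, and the lesser ridge and melanocyte lists in 1 of 32 each.

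In all, 1972 of 10088 genes were higher in HC and 2669 lower with an adjusted p under 0.05 (46%), 1025 and 1088 of them at least 2-fold and 278 and 13 at least 8-fold. Without HC replicate D the counts were 1874 and 2725 and the 7 list calls held. Without the genes of the endothelium, glia, pericyte, mesenchyme, erythroid and macrophage lists they were 1955 and 2660 of 10010. With the beadchip as a block they were 1828 and 2438, within beadchip 1 1368 and 1691, and within beadchip 2 842 and 584. Mean differences of the called lists with the beadchip as a block, within beadchip 1 and within beadchip 2 were 4.15, 4.17 and 4.26 for hair cells, 2.13, 2.10 and 2.21 for ribbon synapses, 1.36, 1.99 and 0.04 for endothelium, and -0.75, -0.75 and -0.78 for epithelium. For the Wnt list they were -0.71, -0.89 and -0.49 (adjusted p = 0.084 within beadchip 2), for GER -1.27, -1.50 and -0.97, and for stem cell-associated genes -0.79, -0.89 and -0.57 (adjusted p = 0.13 within beadchip 2). The calls of the hair cell and ribbon synapse lists held with an estimated correlation, and the fry test, which asks if the genes of a list move 1 way on balance and not how they compare with other genes, passed for all 7. It also passed for lists not called here: lesser ridge (adjusted p = 3e-05), tectorial membrane (4e-06), Notch (0.0036), Fgf (0.00019), Cdk inhibitors (0.0017), macrophage (0.028), neuron (4.6e-08), bone and cartilage (5.8e-05) and melanocyte (0.029). Passing fry thus does not single out the 7.

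GER and DC were compared with each other to ask how the medial ridge cells differ from the Deiters' and Claudius gate. DC held far more of the genes known from Deiters' and pillar cells. Npy, which encodes neuropeptide Y, was 18.4-fold higher in DC (GER minus DC -4.21 ± 0.32, adjusted p = 4.1e-05), and Prox1, a transcription factor of Deiters' and pillar cells, 13.1-fold (-3.71 ± 0.47, adjusted p = 0.00075; detected on 2 of 3 GER arrays). Igfbpl1, which encodes a protein related to the binding proteins of insulin-like growth factors, was not well above background on any GER array and at least 13.1-fold higher in DC (adjusted p = 1.8e-06). In the other direction Stmn2, a microtubule regulator of growing neurites, was 6.39-fold higher in GER (2.68 ± 0.31, adjusted p = 0.00041, 3 GER arrays against 2 DC arrays).

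Of 12 pillar cell genes, 0 were higher in GER, 10 were higher in DC and 2 did not pass (0 and 11 adjusted over the list alone; mean -2.56, adjusted p = 2.1e-23, and adjusted p = 0.0041 with an estimated correlation). S100b, a calcium-binding protein, was at least 3.37-fold higher in DC (adjusted p = 0.00023). The Deiters cell list of 13 also had 0 and 10, with 3 that did not pass (0 and 13 adjusted over the list alone; mean -2.05, adjusted p = 2.7e-20, and adjusted p = 0.0041 with an estimated correlation). Smagp, a small transmembrane glycoprotein, was 7.95-fold higher in DC (-2.99 ± 0.30, adjusted p = 0.00016). Of 11 Fgf pathway genes, 0 were higher in GER, 6 higher in DC and 5 did not pass (0 and 7 adjusted over the list alone; mean -1.28, median -1.05 or -0.50 at the bounds, adjusted p = 1.4e-06, and adjusted p = 0.0086 with an estimated correlation). Fgfr3, the receptor of pillar cell differentiation, was at least 6.54-fold higher in DC (adjusted p = 0.0031), and the Fgf-induced factors Etv4 (16.4-fold, -4.03 ± 0.33, adjusted p = 4.9e-05) and Etv5 (at least 5.05-fold, adjusted p = 0.0021) followed the same direction. Fgfr3, Etv4 and Etv5 are on the pillar cell list too. Of the pillar, Deiters and Fgf genes, 8 of 12, 7 of 13 and 4 of 11 stand in another list, so these calls are not separate results. The supporting cell list of 16, 15 of which stand in another list too, had 0 and 5 with 11 that did not pass (1 and 7 adjusted over the list alone; mean -0.85, adjusted p = 7.1e-05, but adjusted p = 0.17 with an estimated correlation). Hey2, which stands in the pillar cell and Notch lists too, was 3.87-fold higher in DC (-1.95 ± 0.19, adjusted p = 0.00013).

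The GER list itself did not separate the populations: of 12 genes 0 were higher in GER, 1 higher in DC and 11 did not pass (0 and 2 adjusted over the list alone; mean -0.03, adjusted p = 0.72). Crabp1, a retinoic acid-binding protein with the largest difference of that list, had 2.21 ± 0.85 (adjusted p = 0.24, but under 0.05 in 5 of 27 alternatives, with a range of 0.0038 to 0.72), and the 1 that passed, Fst, was 4.36-fold higher in DC (-2.13 ± 0.35, adjusted p = 0.0036). Of 12 genes of the lesser epithelial ridge, Claudius cells and outer sulcus, 0 were higher in GER, 1 higher in DC and 11 did not pass (0 and 2 adjusted over the list alone; mean -0.17, adjusted p = 0.98). That 1, Bmp4, a marker of the lateral epithelium, was 6.77-fold higher in DC (-2.76 ± 0.44, adjusted p = 0.0032). Among 22 Notch genes 0 and 1 passed (mean -0.25, adjusted p = 0.079), among 29 Wnt genes 0 and 3 (mean -0.04, adjusted p = 0.95). Among 24 cell cycle genes limma called 0 and 0, also at an unadjusted p under 0.05 (mean 0.06, adjusted p = 0.93). Among 34 hair cell genes it called 1 and 3 (mean -0.24, adjusted p = 0.084). The hair cell list passed in 3 of 29 alternatives, among them without GER B (mean -0.27, adjusted p = 0.034), and had a mean of -0.34 without DC B. The Notch list passed in 4 of 29, among them quantile without background correction and the deposited log2 values, which gave the same result (adjusted p = 0.048). Among the called hair cell genes, Calb2, which encodes calretinin, was 3.7-fold higher in DC (-1.89 ± 0.21, adjusted p = 0.00029), and Espn, an actin bundler, 2.4-fold higher in GER (1.26 ± 0.21, adjusted p = 0.0036). Without DC B the calls of Fst (-2.04, adjusted p = 0.066), Bmp4 (-2.46, adjusted p = 0.071) and Espn (1.21, adjusted p = 0.066) were lost.

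Lists of other cell types moved with this comparison. Of 23 macrophage genes, 0 were higher in GER, 2 higher in DC and 21 did not pass (0 and 4 adjusted over the list alone; mean -0.65, adjusted p = 0.00043, but adjusted p = 0.35 with an estimated correlation). Trem2, a microglial and macrophage receptor, was at least 1.84-fold higher in DC (adjusted p = 0.0032, but 0.066 without DC B). Of 19 mesenchyme genes, 0 and 2 passed and 17 did not (0 and 2 adjusted over the list alone; mean -0.52, adjusted p = 0.026, but adjusted p = 0.32 with an estimated correlation, and adjusted p = 0.17 with a mean of -0.42 without DC A). Pdgfra, a growth factor receptor of mesenchyme, was 2.43-fold higher in DC (-1.28 ± 0.19, adjusted p = 0.002). None of the 14 endothelium genes passed in either direction by limma (4 higher in GER and 1 higher in DC at an unadjusted p under 0.05), and the list was called higher in GER (mean 0.83, adjusted p = 0.015, but adjusted p = 0.73 with an estimated correlation). Without GER C its mean was 0.36 (adjusted p = 0.29), and within beadchip 1 it was 0.36 (adjusted p = 0.081). It did not pass by fry (adjusted p = 0.38) or with probes detected on at least 4 arrays (adjusted p = 0.056) either.

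In all, 90 genes were higher in GER and 330 higher in DC (4.2% of 10088), 59 and 284 at least 2-fold and 0 and 17 at least 8-fold. Without HC replicate D, which enters through the pooled variance, the counts were 121 and 374. The counts depended on the DC arrays: without DC B they were 15 and 126, without DC A 30 and 184, and the genes higher in GER numbered 54 without GER C and 57 without GER B. Of the 10 genes highest in GER, 9 lost their call without at least 1 array and Stmn2 kept it, while the 10 highest in DC kept theirs without any 1 array. With the beadchip as a block the counts were 76 and 300, and within beadchip 1 79 and 278; beadchip 2 holds no DC array. The mean differences of the called lists as a block and within beadchip 1 were -2.47 and -2.41 for pillar cells, -1.98 and -1.95 for Deiters cells, -1.25 and -1.22 for Fgf, -0.82 and -0.72 for supporting cells, -0.66 and -0.68 for macrophages, -0.60 and -0.53 for mesenchyme, and 0.76 and 0.36 for endothelium. The pillar, Deiters and Fgf calls held with an estimated correlation, and fry passed for 4 of the 7 called lists.

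CD271high was compared with HC, GER and DC to ask what the GFP-negative cells with the most CD271 are. Macrophage genes were far higher in CD271high. C1qc, a chain of complement C1q, was 198-fold higher (7.63 ± 0.31, adjusted p = 3.8e-09, 3 arrays against 9; detected on 1 of the 9), Mrc1, the macrophage mannose receptor, 151-fold (7.24 ± 0.29, adjusted p = 3.5e-09), and Csf1r, the receptor of macrophage colony-stimulating factor, 117-fold (6.87 ± 0.34, adjusted p = 1.7e-08; detected on 2 of the 9). With so few of the 9 arrays above detection, the folds of C1qc and Csf1r are uncertain. Genes of myelinating glia and of dividing cells were higher as well, though these list calls were lost with an estimated correlation (adjusted p = 0.30 and 0.18). Genes of hair cells and of supporting cells were lower, the supporting cell call being lost with an estimated correlation (adjusted p = 0.12). Otof was not well above background on any CD271high array and at least 9.65-fold lower (adjusted p = 1.8e-08), and Sox2, a transcription factor of supporting cells, was 4.73-fold lower (-2.24 ± 0.20, adjusted p = 2.2e-06).

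All 23 measured macrophage genes were higher (23 and 0 adjusted over the list alone; mean 5.96, adjusted p = 1.8e-25, and adjusted p = 0.023 with an estimated correlation). Lyve1, a hyaluronan receptor of tissue macrophages, was at least 38.9-fold higher (adjusted p = 1.1e-09), and the probe of Lyz2, at least 44.8-fold higher, cannot be separated with certainty from its near-identical paralog Lyz1. With such genes at their bounds the median of the list was 5.37. Of 24 cell cycle genes, 23 were higher, 0 lower and 1 did not pass (23 and 0 adjusted over the list alone; mean 2.06, adjusted p = 5.1e-11, but adjusted p = 0.18 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was 13.2-fold higher (3.72 ± 0.38, adjusted p = 8.5e-06; detected on 1 of the 9), and Mcm5, a replication helicase subunit, 7.91-fold (2.98 ± 0.35, adjusted p = 2.8e-05). Of 15 Schwann and satellite glia genes, 12 were higher, 2 lower and 1 did not pass (13 and 2 adjusted over the list alone; mean 2.53, adjusted p = 0.00015, but adjusted p = 0.30 with an estimated correlation). Mbp, which encodes myelin basic protein, was 31.6-fold higher (4.98 ± 0.65, adjusted p = 6.1e-05).

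**Figure D2:**
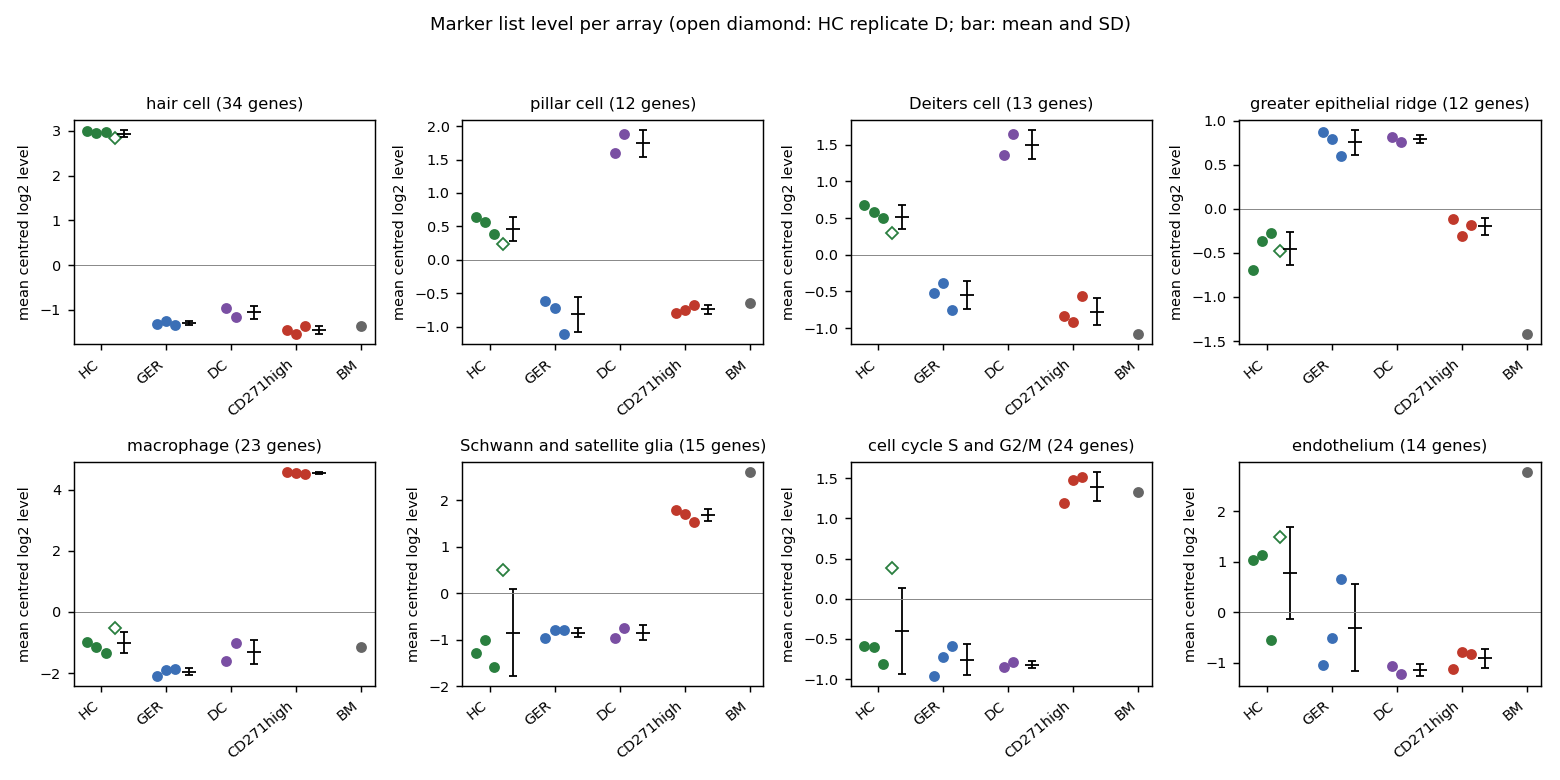
Mean centred log2 level of 8 gene lists on each of the 13 arrays by population; bars give the mean and SD, and HC replicate D is an open diamond. The 3 CD271high arrays lie between 4.51 and 4.57 for macrophages, and HC replicate D lies at 0.50 for glia.

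Bone and cartilage genes were higher in 7 of 9, lower in 0 and did not pass in 2 (7 and 1 adjusted over the list alone; mean 1.25, adjusted p = 0.012, but adjusted p = 0.12 with an estimated correlation and 0.073 against GER alone, where the mean was 0.91). Its largest member, Spp1, encodes osteopontin, which macrophages make too, and was 22.2-fold higher (4.47 ± 0.50, adjusted p = 1.9e-05; detected on 2 of the 9). Of 19 mesenchyme genes, 9 were higher, 0 lower and 10 did not pass (10 and 0 adjusted over the list alone; mean 0.74, adjusted p = 0.029, but adjusted p = 0.32 with an estimated correlation). Col3a1, a fibrillar collagen, differed by 3.17 ± 0.77 (adjusted p = 0.0054), and by 2.51 against DC alone (adjusted p = 0.1). The mesenchyme list no longer passed against DC alone (mean 0.41, adjusted p = 0.17), with probes detected on at least 4 arrays (mean 0.63, adjusted p = 0.13), without CD271high A (mean 0.59, adjusted p = 0.16) or without the BM array (mean 0.73, adjusted p = 0.054). Of 19 genes of the dissociation response, 7 were higher, 2 lower and 10 did not pass (10 and 2 adjusted over the list alone; mean 0.81, adjusted p = 0.018, but adjusted p = 0.75 with an estimated correlation and adjusted p = 0.11 without CD271high B, where the mean was 0.54). The dissociation list also lost its call against GER alone (mean 0.58, adjusted p = 0.062) and against DC alone (mean 0.56, adjusted p = 0.12). Egr2, an immediate-early factor that also drives myelination, was 6.73-fold higher (2.75 ± 0.54, adjusted p = 0.0013).

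Supporting cell genes were lower in 15 of 16 and higher in 1 (1 and 15 adjusted over the list alone; mean -1.39, adjusted p = 6.2e-06, but adjusted p = 0.12 with an estimated correlation). Jag1, a Notch ligand of supporting cells, differed by -2.54 ± 0.26 (adjusted p = 7.9e-06) and Gjb6, the gap junction protein connexin 30, by -2.25 ± 0.15 (adjusted p = 1.8e-07). Of 22 Notch genes, 1 was higher, 14 lower and 7 did not pass (1 and 14 adjusted over the list alone; mean -1.04, adjusted p = 0.00027, and adjusted p = 0.022 with an estimated correlation). Hes5, a Notch target, was 7.1-fold lower (-2.83 ± 0.31, adjusted p = 1.3e-05; detected on 1 of 3 CD271high arrays). Of 13 Deiters cell genes, 1 was higher, 11 lower and 1 did not pass (1 and 11 adjusted over the list alone; mean -1.26, adjusted p = 0.0027, but adjusted p = 0.18 with an estimated correlation). Of 12 pillar cell genes, 0 were higher, 9 lower and 3 did not pass (0 and 10 adjusted over the list alone; mean -1.20, adjusted p = 0.0027, but adjusted p = 0.21 with an estimated correlation). Against GER alone the Deiters mean was -0.22 (adjusted p = 0.71) and the pillar mean turned to 0.08 (adjusted p = 0.62). Of 13 stem cell-associated genes, 2 were higher, 8 lower and 3 did not pass (2 and 8 adjusted over the list alone; mean -0.75, adjusted p = 0.044, but adjusted p = 0.29 with an estimated correlation). This list lost its call in 12 of 33 alternatives, among them against HC alone (mean -0.29, adjusted p = 0.46) and without HC D, GER C or CD271high C (adjusted p = 0.069, 0.063 and 0.073). Lgr5, a Wnt target and marker of progenitors, was 4.1-fold lower (-2.03 ± 0.21, adjusted p = 7.4e-06).

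Hair cell genes were lower in 27 of 34, higher in 1 and did not pass in 6 (1 and 27 adjusted over the list alone; mean -1.65, median -1.53 or -1.02 at the bounds, adjusted p = 5.6e-11, and adjusted p = 0.0086 with an estimated correlation). Most of this lay in the HC arrays: the mean was -0.16 against GER alone (adjusted p = 0.46) and -0.40 against DC alone (adjusted p = 0.15). Ribbon synapse genes were lower in 11 of 18, higher in 0 and did not pass in 7 (0 and 11 adjusted over the list alone; mean -1.22, adjusted p = 0.00027, and adjusted p = 0.022 with an estimated correlation), with -0.46 (adjusted p = 0.16) and -0.55 (adjusted p = 0.17) against GER and DC alone. Of 16 neuron genes, 3 were higher, 9 lower and 4 did not pass (3 and 10 adjusted over the list alone; mean -0.67, adjusted p = 0.039, but adjusted p = 0.18 with an estimated correlation); Syt1, a synaptic vesicle protein, differed by -2.94 ± 0.24 (adjusted p = 1.4e-06). The neuron call rested on the HC arrays, with a mean of -0.40 against GER alone (adjusted p = 0.46) and -0.07 against DC alone (adjusted p = 0.97). It was lost in 7 of 33 alternatives, 1 of them without HC replicate D (mean -0.67, adjusted p = 0.05).

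The epithelium list did not pass in CD271high, and its score there lay between those of GER and DC. Of 17 epithelium genes, 6 were higher, 1 lower and 10 did not pass (5 and 1 adjusted over the list alone; mean 0.24, median 0.00, adjusted p = 0.30, but adjusted p = 0.0014 by fry). The mean list score was 0.48 in CD271high, 0.45 in GER, 0.56 in DC, -0.31 in HC and -2.68 on the BM array. The mean difference was 0.79 against HC alone (adjusted p = 0.015), 0.03 against GER alone (adjusted p = 0.98) and -0.08 against DC alone (adjusted p = 0.86). Other lists that did not pass included Wnt with 9 of 29 higher and 9 lower (mean -0.11, adjusted p = 0.92), the lesser ridge list with 2 of 12 higher and 6 lower (mean -0.77, adjusted p = 0.098) and the GER list with 2 of 12 higher and 5 lower (mean -0.57, adjusted p = 0.70). Fgf had 2 of 11 higher and 5 lower (mean -0.72, adjusted p = 0.22) and endothelium 1 of 14 higher and 4 lower (mean -0.69, adjusted p = 0.30).

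In all, 1959 genes were higher in CD271high and 2439 lower (43.6% of 10088), 1117 and 989 at least 2-fold and 221 and 51 at least 8-fold. Without HC replicate D the counts were 2046 and 2476. With the beadchip as a block they were 2001 and 2497, within beadchip 1 1753 and 1961, and within beadchip 2 725 and 823. Beadchip 2 holds no DC array, so within it CD271high was set against HC and GER only, which is another comparison. The mean differences of the lists as a block, within beadchip 1 and within beadchip 2 were 5.97, 5.96 and 6.01 for macrophages, 2.06, 2.25 and 1.65 for the cell cycle, and 2.54, 2.62 and 2.55 for glia. They were 1.26, 1.26 and 1.48 for bone and cartilage, 0.75, 0.66 and 1.16 for mesenchyme, and 0.81, 0.83 and 0.93 for the dissociation response. Lists lower in CD271high had -1.65, -1.68 and -2.25 for hair cells, -1.22, -1.22 and -1.54 for ribbon synapses, -1.04, -1.02 and -1.06 for Notch, -1.40, -1.43 and -1.01 for supporting cells, and -0.66, -0.64 and -0.97 for neurons (adjusted p = 0.064 within beadchip 1). Deiters genes had -1.27, -1.32 and -0.69 (adjusted p = 0.12 within beadchip 2), pillar genes -1.21, -1.28 and -0.45 (adjusted p = 0.38 within beadchip 2), and stem cell-associated genes -0.75, -0.72 and -0.56, which did not pass in any of the 3 (adjusted p = 0.055, 0.12 and 0.12). Within beadchip 2, with 1 CD271high array, Mbp (4.81), Top2a (3.23), Mcm5 (2.56), Col3a1 (2.74) and Egr2 (2.52) did not pass (adjusted p = 0.085 to 0.37). The macrophage, hair cell, ribbon synapse and Notch calls held with an estimated correlation, and fry passed for 13 of the 14 called lists, all but the dissociation response (adjusted p = 0.084).

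**Figure D3:**
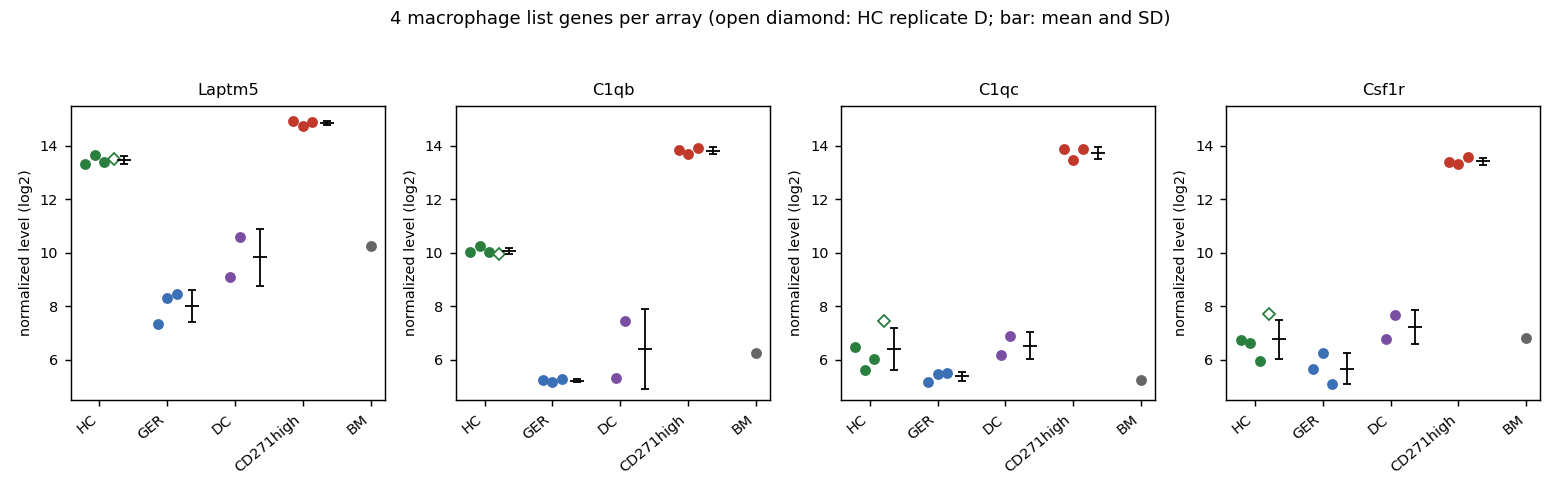
Normalized log2 level of 4 macrophage list genes on each of the 13 arrays by population; bars give the mean and SD, and HC replicate D is an open diamond. The means in HC and CD271high were 13.48 and 14.85 for Laptm5, 10.07 and 13.83 for C1qb, 6.40 and 13.74 for C1qc, and 6.77 and 13.43 for Csf1r.

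The BM array was set beside GER and DC to describe the cells from below the basilar membrane. With 1 array there is no error and no test, so values are given against the range of the 5 GER and DC arrays. Transcripts of mesenchyme and vessels were higher: Col3a1 was 57.7-fold higher than the mean of GER and DC and Emcn, an endothelial sialomucin, 52.4-fold. The highest genes were Fzd10, a Wnt receptor (at least 80.8-fold), Notum, an enzyme that inactivates Wnt proteins (130-fold; detected on 2 of 5 GER and DC arrays), and Ibsp, a bone sialoprotein (at least 48.4-fold). Among the lowest were Wnt7a, a Wnt ligand of the epithelium (at least 34.5-fold lower), Krt18, a keratin (at least 19.5-fold lower), and Grhl2, a transcription factor of epithelial identity (at least 18.7-fold lower).

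Of 19 mesenchyme genes, 17 lay above the range and 1 below, with a median log2 difference of 4.14, or 3.56 with undetected sides at their bounds, higher than all 10000 random lists of genes with like levels (percentile 100). Percentiles are of the medians without bounds. All 14 endothelium genes lay above it (median 3.23, percentile 100), and 13 of 15 glia genes lay above and 1 below (median 3.39, percentile 100). Of 5 pericyte genes, 4 lay above and 1 below (median 3.73, at the bounds 2.16, percentile 99.94), with Rgs5, a regulator of G protein signalling in pericytes, at least 35.3-fold higher. All 24 cell cycle genes lay above the range (median 2.02, at the bounds 1.75, percentile 100), and of 9 bone and cartilage genes 5 lay above and 3 below (median 3.21, at the bounds 2.29, percentile 100). Of 23 macrophage genes, 10 lay above and 2 below (median 0.43, at the bounds 0.23, percentile 96.32). Epithelium genes were below the range in 16 of 17 and above it in 0 (median -3.51, at the bounds -3.04, percentile 0). The GER list had 9 of 12 below and 1 above (median -2.40, at the bounds -2.18, percentile 0), the lesser ridge list 10 of 12 below and 1 above (median -2.15, at the bounds -1.41, percentile 0). The Deiters list had 7 of 13 below and 1 above (median -2.13, at the bounds -1.26, percentile 0) and the supporting cell list 11 of 16 below and 2 above (median -1.02, percentile 0). The Wnt list, though it holds Fzd10, had 16 of 29 below the range and 7 above (median -0.46, at the bounds -0.45, percentile 0.3). The medians of the pillar, Notch, Fgf and stem cell-associated lists were -0.84, -0.59, -0.83 and -0.89 (percentiles 0.2, 0.27, 0.42 and 0.13). The hair cell list stayed near GER and DC, with 4 of 34 above and 11 below (median -0.09, percentile 26.16).

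In all, 1265 genes lay at least 2-fold above and outside the range of the 5 arrays and 1252 at least 2-fold below, 303 and 235 of them at least 8-fold. The BM value was outside the range for 64.7% of genes, where chance gives 33.3%. Without background correction the counts were 816 and 740. The list medians were then 2.73 for mesenchyme, 1.84 for endothelium, 2.97 for glia, 1.85 for pericytes, 1.30 for the cell cycle, 1.68 for bone and cartilage and -2.40 for epithelium. The macrophage median turned to -1.30 when BM was set against HC, GER, DC and CD271high. Over the alternatives 52 BM gene values moved by more than the SD of the GER and DC arrays and 48 did not. Of the list medians 58 moved and 77 did not.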

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

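The tests of explanations given here, on the glial transcripts of HC replicate D, were chosen only after the result was seen. For the 4 HC arrays, 122 measures were checked for 1 array far from the other 3, namely 27 list scores, 92 genes and 3 array measures. Chance alone marks about 1 in 20 groups, 6.1 of these, and 11 were found, 6 of them in HC replicate D. The measures are not independent, since lists and their own member genes were checked on the same 4 arrays. The 11 therefore cannot be judged against the 6.1.

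HC replicate D held more transcripts of the pericyte, mesenchyme and tectorial membrane and matrix lists than the other HC arrays. The Deiters, pillar, supporting cell, GER and epithelium lists were not raised above the other HC arrays in replicate D. Its pericyte list score was 1.26 against -0.80 to -0.62 on the others, its mesenchyme score 0.02 against -0.81 to -0.70, and its tectorial membrane and matrix score -0.21 against -0.55 to -0.51. The same array stood apart in Rgs5, a pericyte gene (10.14 against 5.43 to 5.61), Mcm5, a replication gene (10.09 against 8.17 to 8.46), and Col11a1, a fibrillar collagen (6.82 against 5.78 to 5.94).

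The pattern weighed, the glial list, is not among the 11, since its gap was too small for that check; it stood at 0.50 in HC D against -1.60 to -1.01, with Mbp at 12.18 in HC D against 8.05 to 9.63. A difference between the beadchips is argued against, since HC B and C share the beadchip of D and D lay 1.81 above their mean (SD 0.42). RNA of other cells may have entered this sort despite the GFP gate that would remove them: of 249 genes outside the lists at least 8-fold higher in BM than in GER and DC, 74.7% were higher in D than in each of A to C, against 29% of 2291 genes of like level within 2-fold, and for no other HC array was the share over 16.5%. The median share of BM-like RNA that the levels would need was 13.1% for glia (10 genes, 7.74% to 29.4%) and 22.3% for pericytes (3 genes, 2.54% to 41.1%). It was 4.09% for mesenchyme (13 genes, 0.255% to 19.7%), 8.47% for endothelium (2 genes) and 25.7% for the cell cycle (4 genes). That of CD271high-like RNA was 17.2% for glia (10 genes, 9.19% to 66.3%), 68.7% for mesenchyme (2 genes) and 25.9% for the cell cycle (6 genes), but 1.02% for macrophages (21 genes). Most of these shares rest on few genes with wide ranges, so the mixture of cells stays open. Of the 15 glial genes, 5 stand in another list and 9 were detected on all GER and DC arrays, and no biological explanation was tested.

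The remaining values are given without an explanation. HC replicate B had a melanocyte and stria vascularis score of 0.38 against -0.45 to -0.41, a Hey1 level of 13.39 against 12.95 to 12.97 and an S100a1 level of 14.88 against 14.69 to 14.70. HC replicate C had a Hes1 level of 8.28 against 9.01 to 9.10 and an Esam level of 8.20 against 10.67 to 11.15.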

How the results depend on the processing

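The alternative without the genes of other cell types was chosen, and HC replicate D singled out among the planned left-out arrays, after seeing the data. Of the genes named for HC, GER against DC and CD271high, 2445, 1992 and 2439 results under the alternatives that leave no array out kept direction and side of the threshold, 114, 49 and 134 lost the call, 30, 59 and 27 gained one, and 17, 0 and 11 turned. Of the list results 479, 416 and 491 kept both, 9, 9 and 36 lost the call, 23, 7 and 12 gained one, and 2, 0 and 1 turned. With 1 array left out, 1925, 1830 and 1829 gene results kept both, 43, 91 and 45 lost the call, and 18, 22 and 6 gained one. Of the BM values, 52 for genes moved and 48 did not, and 58 for lists moved and 77 did not. These tallies count quantile without background correction and the deposited log2 values separately, though both gave the same counts. Genes near background limit the folds to lower bounds. GER against DC could not be run within beadchip 2, which holds no DC array. There HC was set against GER only and CD271high against HC and GER. Where 1 array of a group was left it was assumed to vary like the others.

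A 2-fold minimum, which can only lower counts, left 1025 higher and 1088 lower in HC, 59 higher in GER, and 1117 and 989 in CD271high. Within beadchip 2, with fewer arrays, HC had 842 and 584 and CD271high 725 and 823, and within beadchip 1 HC had 1691 lower. CD271high had 1231 and 1288 against DC alone and 1623 lower against GER alone; GER had 187 higher with array weights; BM had 816 and 740 without background correction and also with the deposited log2 values. The cause was not tested.

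Leaving out each array in turn gave 1702 (without DC A) to 1970 higher and 2218 to 2725 lower for HC, 15 (without DC B) to 121 (without HC D) higher in GER and 126 (without DC B) to 374 lower, with 30 and 184 without DC A, 54 higher without GER C and 57 without GER B, and 1633 to 2046 higher and 1964 to 2476 lower for CD271high. With the letters as a replicate block the counts were 1872 and 2711, 104 and 353, and 2049 and 2458. Over 15 same-letter pairs the mean r of the residuals was 0.043 (-0.126 to 0.183), with 4 pairs over 0.1. Over 38 other-letter pairs it was -0.017 (-0.278 to 0.189). The residuals are centred within populations of 2 to 4 arrays, so these values cannot decide whether the letters pair the arrays.

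Directions turned as follows; the cause was not tested. CD271high against HC alone: Bmp4 0.45, Col9a3 0.347, Fst 0.11. Against GER alone: Cdkn2d 0.211, Etv4 0.536, Fgfr3 0.558, Nefm 0.045, and the pillar list 0.079. Against DC alone: Cldn4 -0.188, Cldn5 0.139. Within beadchip 2: Cdkn1b 0.247, Fgfr3 0.342. HC within beadchip 2: Cd44 0.207, Cldn5 -0.2, Hey1 0.003, Hey2 0.716, Plvap -0.3, Robo4 -0.02, Shisal2b 0.268, Sox18 -0.189, Trem2 0.216. HC against GER alone: Gjb1 0.581, Hey2 0.435, Ngfr 0.792, Shisal2b 0.648, Trem2 0.239. HC against DC alone: Lhfp -0.043, Mcam 0.757, Npy -1.025, the Deiters list -0.986, the pillar list -1.279.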

Other observations

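The tests of explanations for Ngfr, Laptm5 and C1qb and the counts over other splits of the arrays were chosen only after the results were seen. In HC the lists of the neighbouring supporting cells lay between GER and DC. The pillar cell list, with 2 of 12 higher, 3 lower and 7 that did not pass, had a mean of 0.00 against GER and DC together (adjusted p = 0.92), 1.28 against GER alone (adjusted p = 0.0021) and -1.28 against DC alone (adjusted p = 0.00095; 0.00022 to 1 over its alternatives). The Deiters cell list, with 2 of 13 higher, 3 lower and 8 that did not pass, had 0.04 (adjusted p = 0.88), 1.07 (adjusted p = 0.0023) and -0.99 (adjusted p = 0.011; 0.00035 to 0.97 over its alternatives). S100a1, a calcium-binding protein of both lists and of the supporting cell list, was higher in HC (0.61 ± 0.14, adjusted p = 0.0044), but not against DC alone (0.11, adjusted p = 0.68; 0.00017 to 0.68 over its alternatives), and Prox1 had 0.67 ± 0.35 (adjusted p = 0.14). The supporting cell list had 1 of 16 higher and 5 lower, with a mean of -0.11, a median of 0.02 and an adjusted p of 0.92.

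Lists of gap junctions, tectorial membrane and stria vascularis did not pass in CD271high, and their members went both ways. Of 7 gap junction genes in CD271high, 2 were higher, 2 lower and 3 did not pass (mean -0.18, median 0.16, adjusted p = 0.94): Gjb2, the connexin gene most often mutated in deafness, was 2.88-fold lower (-1.53 ± 0.14, adjusted p = 4.2e-06), while Gja1, connexin 43, was 1.83-fold higher (0.87 ± 0.27, adjusted p = 0.019). The Gja1 call was lost in 5 of 31 alternatives (adjusted p = 0.0038 to 0.54), among them against GER alone (0.47, adjusted p = 0.32), against DC alone (0.89, adjusted p = 0.097), within beadchip 2 and without CD271high B or C. Of 11 tectorial membrane and matrix genes there, 3 were higher, 3 lower and 5 did not pass (mean 0.18, median -0.42, adjusted p = 0.94, with the test pointing down). Tecta, the main tectorin, was 1.58-fold lower (-0.66 ± 0.10, adjusted p = 0.00017, but 0.13 within beadchip 2 and 1.3e-07 to 0.13 over its alternatives) and Otoa, which attaches the membrane, 2.77-fold higher (1.47 ± 0.13, adjusted p = 3e-06). Of 8 melanocyte and stria vascularis genes, 2 were higher, 1 lower and 5 did not pass (mean -0.26, adjusted p = 0.87). Kcnq1, a strial potassium channel, was 2.35-fold higher (1.24 ± 0.16, adjusted p = 6.6e-05; detected on 4 of the 9 other arrays). Of 8 Cdk inhibitor genes, 1 was higher, 3 lower and 4 did not pass (mean 0.01, median -0.11, adjusted p = 0.93), with Cdkn2c 6.28-fold higher (2.65 ± 0.33, adjusted p = 4.1e-05; detected on 2 of the 9 other arrays). The 2 erythroid genes did not pass (mean 0.17, adjusted p = 0.92), and of 3 sort marker genes 0 were higher and 1 lower (mean -0.59, adjusted p = 0.86). In GER against DC the mean and the test of the melanocyte list (0.05, adjusted p = 0.96) differed in sign, as did the median and the test of the glial list (0.23, adjusted p = 0.92).

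Ngfr was lower in CD271high, the cells sorted for the most CD271, than in HC, GER and DC together, but against GER alone only by -0.82 (adjusted p = 0.07; 3.8e-06 to 0.13 over its alternatives), so most of the difference lay in DC and HC. A probe without signal is argued against, since it was detected on all 13 arrays and GER and DC differed by -2.67 (SE 0.35). The macrophage list was 5.85 (SE 0.28) higher in CD271high than in DC. This cannot decide whether the CD271high and DC labels were exchanged. The labels call CD271high only suspected macrophages, and Ngfr was highest in DC, which an exchange would give too. Antibody held by Fc receptors may have brought macrophages into the CD271 gate and stays open: the 4 measured Fc gamma receptor genes, undetected on the HC, GER and DC arrays, were higher in CD271high by a median lower bound of 3.08 on the log2 scale (SD 1.63), with Fcgr3 at least 41.4-fold. Macrophages carry these receptors whether or not they hold the antibody, and no protein level is analysed here.

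Laptm5 and C1qb, both on the macrophage list, were high in HC on all 4 arrays. If macrophage RNA in the HC sorts were the likely source, Laptm5 would need a share of 37.4% of CD271high RNA and C1qb 6.98%. The other 21 members lay below the level these shares predict by a median of -4.51 (SD 0.95) and -2.34 (SD 0.73), which argues against it for both genes. C1qc stood at 6.40 in HC against 13.74 in CD271high, and Csf1r at 6.77 against 13.43. Of the 23 macrophage genes 0 stand in another list and 1 was detected on all GER and DC arrays; each of the 2 genes is read by 1 probe, so binding of another transcript stays open, as does transcription in hair cells, neither of which was tested.

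Other splits of the arrays were fitted with HC, or CD271high, against the other arrays pooled. For HC, 1 of 100 splits drawn from 126, the real one, gave as many genes (4516, with 2815 the highest other). That highest other split set GER A, B and C and DC A apart. For CD271high, 2 of 100 splits drawn from 220 gave as many as the real 2352, the real one included. The higher other, 2588, set HC replicates A, B and C apart, which is a structure of the samples. The arrays come from different populations, so other splits hold real differences too. These counts therefore cannot test chance, and no conclusion is drawn from them.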
